A study of Mus musculus with 2 samples.

How the data were processed

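Total RNA of sorted splenic CD4+ helper and CD8+ cytotoxic T cells was labelled with Cy3 by linear amplification, per the labels' protocols, and hybridised to 1 array per cell type. The number of mice behind each array and the surface markers used in the sort are not given in the sources used here. Both arrays lay on 1 slide, per the file headers, so the slide did not separate them.

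The deposited scanner files give each spot's intensity on a linear scale. Per the file headers they were made with Feature Extraction 10.1.1.1, while the submitters' processing notes name Agilent Feature Extraction 9.1. The processed intensity in the deposited files is the Cy3 signal after that software's background subtraction and detrending, with no scaling between the arrays. The authors' value table of the series holds the same arrays, and its intensity equals the spot's median pixel brightness at 45018 of 45018 spots on each array, compared for exact equality. It is therefore linear and neither background-subtracted nor centred, with medians of 80 and 73 for the CD4+ and CD8+ arrays, and the authors' own description of its scaling is not given in the sources used here.

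From these files, the log2 of the processed signal was taken and each array's 75th percentile over non-control probes was subtracted. That percentile corresponded to a processed signal of 508 on the CD4+ array and 449.9 on the CD8+ array, and the medians were 40.6 and 32.6. Of the probes, 57.3% were well above background on both arrays. Control spots were left out, as were spots marked as outliers (99 and 92), and saturated spots (212 on each array) were kept. Spots of a probe were averaged on the log2 scale. A gene took the probe with the highest mean level among those well above background, with preference for a probe above background on both arrays. No gene had probes that differed in sign with each at least 2-fold. Where all probes of a gene were not well above background on an array, the bright level was set against the higher of the dim probe's own level and the lowest level among probes well above background on the dim array, and the difference was given as "at least" that many fold.

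Probes were named through their transcript accession, without version, in a RefSeq gene table of assembly GRCm38.p6, used for names alone because the file headers name another build. Of 41174 probes, 24844 (60.3%) matched 1 symbol, 0 matched several and 16330 matched none. They covered 17176 genes, of which 4118 were not well above background on either array. Of 330 genes in the lists, 20 had no named probe.

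The comparison, the lists and the named genes were fixed before the data were examined. There were 27 lists, 17 of T cell biology and 10 of markers of other cell types, sharing some genes, and the lists with at least 5 members above background were described. Each list's median difference was set against 10000 random lists (2000 in the alternatives) of the same size, matched on mean level in 20 bins, and the central range of these lists runs from the 2.5th to the 97.5th percentile. Genes were named by rule: Cd4, Cd8a and Cd8b1; the 12 largest differences per direction among genes above background on both arrays; the 6 largest bounds per direction among genes of 1 array; the 4 largest per list; and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. The rankings skipped clone names, predicted genes, genes whose probes disagreed and genes saturated on both arrays, and the values of a few genes that the rule names are not reported here. With 1 array per group no p-value was computed, and the number of arrays limits the precision.

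Alternatives were normexp background correction (offset 50), scaling to the median or over detected probes, quantile and loess normalization (span 0.3), the authors' series values, no filter on dim probes or brighter probes alone, saturated probes left out, outlier spots kept, the mean over probes, a 4-fold threshold, 10 bins, and genes measured on both arrays alone. The planned normexp correction on mean signals was run on the median signal and its background median instead, because the scanner files hold no mean signal column. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.

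The computation was tested on simulated data for the comparison of the CD8+ with the CD4+ array, with 200 of 11961 genes changed. A 2-fold threshold recovered 49 of 50 genes at a log2 difference of 1.5, 48 of 50 at -1.5, 50 of 50 at 3 and 2 of 50 at 0.5, and 0 of 11761 unchanged genes passed. The simulated noise gave the difference an SD of 0.23 at every level, so this count does not measure false passes on the real arrays. Of 200 unchanged lists, 12 fell outside the 2.5th to 97.5th percentile, and a list shifted by 0.5 stood at percentile 100.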

Results

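The study measured gene expression in helper T cells, which carry CD4, and in cytotoxic T cells, which carry CD8. The labels describe both as splenocytes of wild-type C57B6 mice isolated by cell sorting. Each cell type was hybridised to 1 one-colour Agilent mouse expression array, so the comparison had no replicates and no test between the cell types was possible. Each array held 45018 spots, of which 43379 were not controls and carried 41174 different probes. On the CD4+ array 27360 of those spots (63.1%) were well above background, and on the CD8+ array 25441 (58.6%) were. Over the 23573 probes well above background on both arrays, the log2 levels correlated across probes with r = 0.985, and probes are not independent replicates. Differences are given as the CD8+ array minus the CD4+ array on the log2 scale, so a positive value means a higher level in the CD8+ array. The only spread available was technical. The log2 difference had an SD of 0.16 between replicate spots of a probe (141 probes) and of 0.23 between different probes of a gene (3972 genes).

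The question, as the design text puts it, was how the expression profiles of the helper and cytotoxic cells differ. Among genes of the cytotoxic program, Nkg7, a protein of cytotoxic granules, was 14.2-fold higher in the CD8+ array, the T-box transcription factor Eomes 10.03-fold and the granzyme gene Gzmm 9.69-fold. In the CD4+ array, Zbtb7b, the transcription factor (ThPOK) that directs thymocytes to the helper lineage, was 19.8-fold higher and the inhibitory receptor gene Ctla4 15.6-fold higher. Il4, a helper cytokine, and Foxp3, the transcription factor of regulatory T cells, were well above background on the CD4+ array alone, at least 29.6-fold and at least 21.3-fold higher there. Several effector genes went the other way from Nkg7, among them Fasl, the death ligand, 10.4-fold higher in the CD4+ array. With normexp, run on the median signal with an offset of 50, 52 of the 133 genes under the naming rule had a fold over 1.5 times smaller, and 40 did with the series values. Zbtb7b was then 10.4-fold, Ctla4 4.78-fold, Il4 at least 6.82-fold, Foxp3 at least 4.14-fold, Eomes 6.46-fold, Gzmm 6.12-fold and Fasl 6.47-fold apart with normexp.

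The genes of the surface proteins that name the cells checked the labels and are no finding. Cd8a, the CD8 alpha chain, was 105.6-fold higher in the CD8+ array (log2 difference 6.72), and its 3 probes gave differences of 6.72, 6.73 and 6.83. Cd4 was 4.12-fold higher in the CD4+ array (log2 difference -2.04, but -1.37 or 2.58-fold with normexp), measured by 1 probe with 10 spots whose processed signal was 307 ± 14.8 (SD over spots) in the CD4+ array and 67.1 ± 12.9 in the CD8+ array. No probe was matched to Cd8b1, so it is not analysed here. The sex-linked genes differed little between the arrays, with log2 differences of -0.07 for Xist, -0.10 for Ddx3y, -0.01 for Eif2s3y, -0.14 for Kdm5d and 0.19 for Uty. The small negative values of Xist, Ddx3y, Eif2s3y and Kdm5d became positive when the arrays were scaled to their medians.

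Of the 17176 genes named on the array, 11961 were well above background on both arrays. Their median log2 difference was 0.02, with an interquartile range from -0.18 to 0.20, and 94.2% lay within 2-fold. At least 2-fold apart were 234 genes higher in the CD8+ array and 458 higher in the CD4+ array, and at least 4-fold apart were 51 and 111. The CD8+ array thus held the higher value for 33.8% of the genes at least 2-fold apart. Scaling each array to its median moved the median of all genes by 0.14 and gave 323 and 366 genes, a CD8+ share of 46.9%. Using brighter probes alone gave 102 and 133 genes, a share of 43.4%. Normexp gave 122 and 220, and the series values gave 140 and 269.

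**Figure D1:**
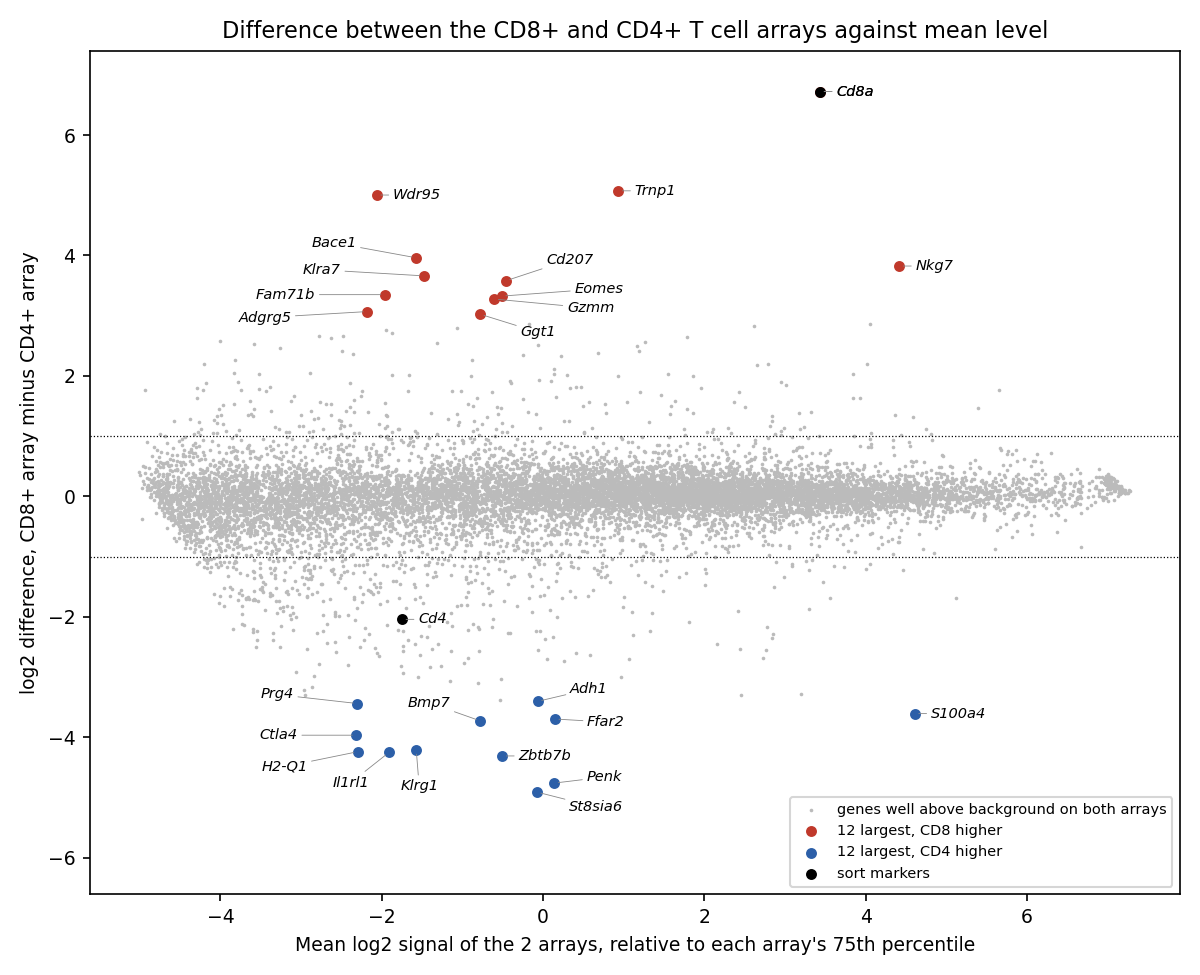
Each grey point is 1 of the 11961 genes well above background on both arrays, with the mean log2 signal relative to each array's 75th percentile on the horizontal axis and the log2 difference, CD8+ array minus CD4+ array, on the vertical axis; dotted lines mark 2-fold, red and blue points are the 12 largest differences per direction and black points the sort markers (Cd8a is both). Cd8a stands highest at 6.72, St8sia6 lowest at -4.91, and most genes lie near 0.

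Among the genes well above background on both arrays with the largest differences in favour of the CD8+ array, after Cd8a, were Trnp1 at 33.7-fold, Wdr95 at 32.1-fold (5.95-fold with the mean over its probes) and Bace1, a membrane protease known for cleaving the amyloid precursor protein, at 15.6-fold. Klra7, a receptor of the Ly49 family found on natural killer (NK) cells, was 12.7-fold higher, but its near-identical relatives leave open which of them its probe measured. Cd207, the C-type lectin langerin of dendritic cells, was 11.96-fold higher. Fam71b followed at 10.2-fold, the adhesion G protein-coupled receptor gene Adgrg5 at 8.39-fold and Ggt1, a gamma-glutamyltransferase, at 8.14-fold. Under normexp Wdr95 had 8.56-fold, Cd207 7.60-fold, Bace1 6.72-fold, Klra7 5.92-fold, Ggt1 5.31-fold, Fam71b 4.01-fold and Adgrg5 3.84-fold.

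Among genes well above background on both arrays, the largest differences in favour of the CD4+ array were those of St8sia6, a sialyltransferase gene, at 30.1-fold, and of Penk, which encodes the opioid precursor proenkephalin, at 27.1-fold. Il1rl1, the interleukin 33 receptor chain, was 19.1-fold higher (11.5-fold with the mean over its probes) and Klrg1, a lectin-like inhibitory receptor, 18.5-fold. H2-Q1, a non-classical MHC class I gene, was 18.9-fold higher, with the same uncertainty over related genes as for Klra7. The growth factor gene Bmp7 was 13.2-fold higher, the short-chain fatty acid receptor gene Ffar2 13.0-fold, the calcium-binding protein gene S100a4 12.2-fold, Prg4 (lubricin) 10.9-fold and the alcohol dehydrogenase gene Adh1 10.6-fold. Under normexp St8sia6 had 15.8-fold, Penk 16.1-fold, Ffar2 8.37-fold, Bmp7 7.70-fold, Klrg1 7.15-fold, Il1rl1 7.09-fold, H2-Q1 4.44-fold and Prg4 4.35-fold.

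A further 178 genes were well above background on the CD8+ array alone and 919 on the CD4+ array alone, and for these the difference has a lower bound. The bound reached 2-fold for 54 and 151 of them. The lowest level among probes well above background was -5.30 on the CD4+ array and -4.94 on the CD8+ array, so the detection limit differed as well. In the CD8+ array the amino acid transporter gene Slc6a19 was at least 25.4-fold higher, followed by Gpr141b (at least 6.72-fold), Wfikkn2 (6.35-fold), the olfactory receptor gene Olfr1233 (6.22-fold), Gulo (4.93-fold) and the cytochrome P450 gene Cyp2b9 (4.54-fold). In the CD4+ array, besides Il4 and Foxp3, the succinate receptor gene Sucnr1 was at least 18.4-fold higher, Ncmap 17.0-fold, the cell adhesion gene Dscam 14.9-fold and P4ha2, a collagen prolyl hydroxylase, 14.8-fold. With normexp, which also replaces the processed by the median signal, 2 and 18 genes had a bound of 2-fold, and with the series values 8 and 25. The normexp bounds were 5.84-fold for Slc6a19 and 2.55-fold for Olfr1233. For Sucnr1 the bound was 4.63-fold, for Dscam 3.91-fold, for Ncmap 3.64-fold and for P4ha2 2.96-fold.

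The gene lists are described by the median log2 difference of their members well above background on at least 1 array and by its percentile among 10000 random lists matched on level, which is a description of these arrays. Helper-associated genes had a median of -1.06 over 12 genes, below every random list. Of these, 7 were at least 2-fold higher in the CD4+ array (4 with median scaling and 5 with normexp) and none in the CD8+ array. Besides Zbtb7b, the costimulatory receptor gene Tnfrsf4 (OX40) was 6.45-fold higher, Cd40lg, the ligand that engages CD40 on antigen-presenting cells, at least 5.39-fold, and the interleukin 2 gene Il2 2.83-fold by its brighter probe and 1.17-fold by the other. With the mean over probes Il2 was 1.82-fold higher and 6 genes of the list passed 2-fold.

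Regulatory T cell genes had the median -2.07 over 16 genes, or -1.90 with genes of 1 array at their bounds, below every random list. At least 2-fold higher in the CD4+ array were 12 of them (11 with the mean over probes), and none was in the CD8+ array. Next to Foxp3 and Ctla4 stood Il2ra, the high-affinity interleukin 2 receptor chain, at least 8.01-fold higher (at least 3.48-fold with the mean over its probes), and Tnfrsf4, which the helper list also holds. The 12 genes of the list measured on both arrays had a median of -1.54. Helper effector cytokines and their regulators had a median of -2.14 over 14 genes, or -1.42 with bounds, again below every random list, with 10 genes at least 2-fold higher in the CD4+ array (9 with the mean over probes). Beside Il4 and Il1rl1 these included the chemokine receptor gene Ccr6, 4.72-fold higher. Follicular helper genes had a median of -0.79 over 11 genes, below every random list. Pdcd1, the inhibitory receptor PD-1, was 4.93-fold higher in the CD4+ array, the transcription factor Maf 4.23-fold, Cd200 2.98-fold and the cytokine gene Il21 at least 2.5-fold. With normexp these 3 medians were -1.25, -0.93 and -0.53. Dendritic, NK and plasma cell markers lay in the same direction as these lists and the helper list, with medians of -0.84, -1.17 and -0.85.

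CD8 transcription factors and identity genes had a median of 0.57 over 10 genes, above every random list. Eomes, the integrin chain gene Itgae (CD103) at 4.57-fold and Crtam, an adhesion receptor of activated cytotoxic cells, at 4.54-fold were at least 2-fold higher in the CD8+ array. Prdm1, the transcription factor Blimp-1, was 4.87-fold higher in the CD4+ array, where the plasma cell markers, a list that also holds Prdm1, were higher too (median -0.85 over 8 genes). NK-type receptors and adaptors had a median of 0.50 over 14 genes, above every random list. The list holds other Ly49 genes besides Klra7, whose probes may not measure separate genes. Klra7 and Klrd1 (CD94), 7.30-fold, were among 4 genes at least 2-fold higher in the CD8+ array (2 with normexp or the series values), and Klrg1, Klrb1c (NK1.1), 5.07-fold, and the adaptor gene Tyrobp, 2.25-fold, were higher in the CD4+ array. B cell and platelet markers lay in the direction of these lists, with medians of 0.51 and 0.59.

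Cytotoxic granule and effector genes were split, and their median of 0.09 over 18 genes stood at percentile 82.3. At least 2-fold higher in the CD8+ array were 6 of them, Nkg7, Gzmm, the granule protease gene Ctsw (4.57-fold), the chemokine gene Xcl1 (3.79-fold), the perforin gene Prf1 (3.32-fold) and the chemokine gene Ccl4 (2.17-fold). At least 2-fold higher in the CD4+ array were 5, Fasl, the granzyme genes Gzmc (7.51-fold, or 2.29-fold with normexp), Gzmb (2.68-fold) and Gzmk (2.20-fold), and the interferon gamma gene Ifng (3.21-fold). With normexp 5 members passed 2-fold in the CD8+ array and 4 in the CD4+ array. The series values and median scaling each gave 6 and 4. Of these 11 genes, those besides Nkg7, Gzmm, Fasl and Gzmc are named because of their values. With brighter probes alone, which kept 13 genes, 6 higher in the CD8+ array by at least 2-fold and 2 in the CD4+ array, the median was 0.56 and lay above every random list. NK cell markers were higher in the CD4+ array, with a median of -1.17 over 5 genes (-0.69 with normexp), of which Ncr1, an activating NK cell receptor, was 4.40-fold higher there.

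Cell cycle genes had a median of -0.51 over 18 genes (-0.31 over 13 with brighter probes alone), below every random list, with Bub1, a kinase of the spindle checkpoint, 2.5-fold higher in the CD4+ array by its brighter probe and 1.49-fold by the other. Bub1 was the only member beyond 2-fold, and with the mean over probes, which put it at 1.93-fold, there was none. Cdk1 (1.83-fold), the cyclin genes Ccna2 (1.74-fold) and Ccnb1 (1.70-fold) lay in the same direction, and 5 members were higher in the CD8+ array. Immediate early and stress genes had a median of -0.35 over 14 genes at percentile 0.020, which was -0.19 with normexp, -0.20 with the series values, -0.21 with median scaling and -0.55 with brighter probes alone. Nr4a1, a nuclear receptor induced by T cell receptor signals, was 2.34-fold higher in the CD4+ array and the phosphatase gene Dusp1 1.97-fold. The plasma, NK and dendritic cell markers, at -0.85, -1.17 and -0.84, lay in the same direction as both lists. MHC class I presentation genes had a median of 0.28 at percentile 99.7 (0.42 with median scaling and 0.18 after quantile normalization), and 10 of 10 members were higher in the CD8+ array (8 after quantile normalization, 9 after loess and 9 of 9 with saturated probes left out). Tap2, a subunit of the peptide transporter, was 1.81-fold higher and the peptidase gene Erap1 1.48-fold. B cell and platelet markers, at 0.51 and 0.59, lay in the same direction as the MHC class I list.

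The remaining T cell lists lay within the central range of their random lists in the main setting. Naive and recirculating T cell genes had a median of 0.08 (percentile 73.0), and none of the 13 was 2-fold apart. The largest difference was that of Dapl1, at 0.84, and Ccr7, a chemokine receptor that guides cells to lymph nodes, had 0.34. CD3 complex and T cell receptor signalling genes had a median of 0.11 (percentile 82.5) but a mean of -0.03, since Trat1, an adaptor of the receptor complex, was 5.47-fold higher in the CD4+ array while the other 15 lay within 2-fold. Cytokine receptor genes had a median of 0.12 (percentile 88.4, but 98.0 with normexp and 98.1 with the series values) and a mean of -0.21, with Il18rap, an interleukin 18 receptor chain, 2.17-fold higher in the CD8+ array and Il2ra and Tgfbr1 (2.22-fold, 1.93-fold with the mean over its probes) higher in the CD4+ array. Chemokine receptor and homing genes had a median of -0.07 (percentile 14.2), positive with normexp, with median scaling, with brighter probes and with genes of both arrays alone. Ccr9, a receptor of gut-homing cells, was 6.28-fold higher in the CD8+ array, and Ccr2 was 6.41-fold and Ccr4 4.61-fold higher in the CD4+ array. Interferon-stimulated genes had a median of 0.04 (percentile 47.3) and a mean of -0.03, and the median turned negative after loess and with the percentile taken over detected probes. Ifit2 differed by -0.80 and Ifit3 by 0.72. Glycolysis genes had a median of 0.09 (percentile 68.0), led by Hk1 at 0.58, and it was negative after quantile normalization. Ribosomal protein genes had a median of 0.17 (percentile 95.8, but 98.2 with 10 bins and 98.6 with the mean over probes). Of the 15 genes, 11 were measured by probes saturated on both arrays, so the size of their differences is not known; leaving out saturated probes kept 5 genes with a median of 0.28 (percentile 97.4), and Rpl4, among the unsaturated ones, differed by 0.57.

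**Figure D2:**
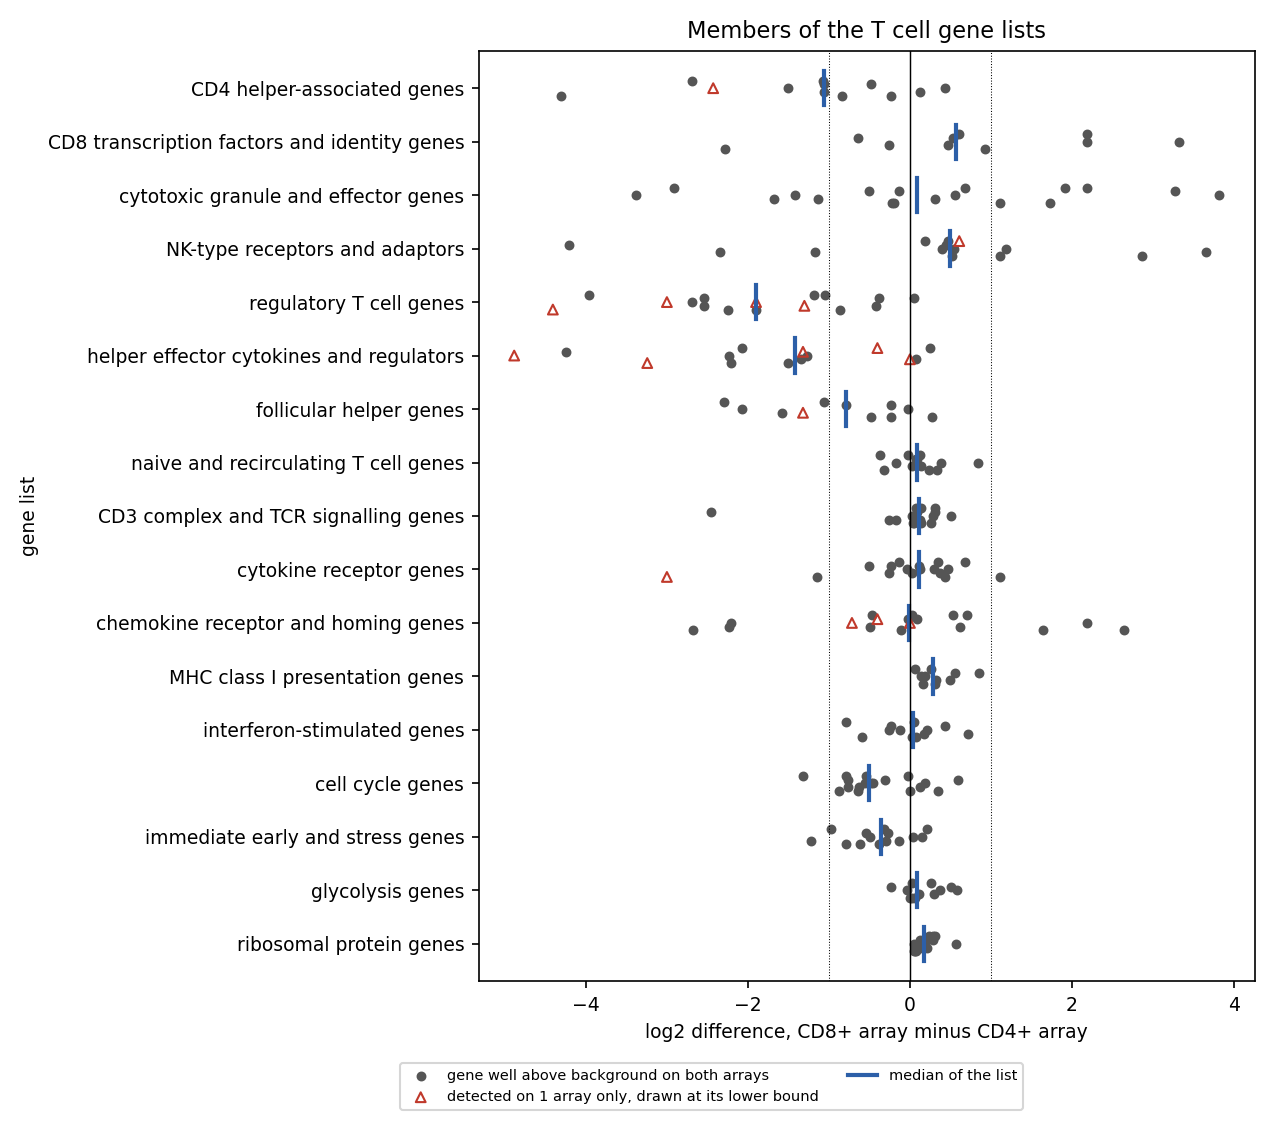
Each row is a T cell gene list and each point a member gene, placed by its log2 difference, CD8+ array minus CD4+ array; open triangles are genes well above background on 1 array alone, drawn at their lower bound (at 0 where the bound gives no fold), blue bars are medians with those bounds and dotted lines mark 2-fold. The regulatory T cell and helper cytokine lists have their medians farthest to the left, at -1.90 and -1.42, and cytotoxic genes spread to both sides.

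Markers of other cell types also differed between the arrays. The B cell markers with a difference of 0.51 were above every random list, none of the 13 was 2-fold apart, and the median was 0.29 with normexp and 0.33 with the series values, but with brighter probes alone the median was 0.12 at percentile 82.1, inside the central range. Cd79b, a signalling chain of the B cell receptor complex, was 1.79-fold higher in the CD8+ array. Dendritic cell markers were below every random list, with the lectin genes Cd209a 9.25-fold and Siglech 6.28-fold and the integrin gene Itgax (CD11c) 2.48-fold higher in the CD4+ array. With normexp Cd209a was 2.55-fold and Siglech 3.26-fold higher there. Macrophage and monocyte markers had a median of -0.17 over 13 genes (percentile 0.79, but -0.09 at 7.35 with normexp and -0.09 at 6.45 with the series values; -0.02 with median scaling), with the lysozyme genes Lyz2 and Lyz1 at 4.49-fold and 3.65-fold and the integrin gene Itgam at 3.11-fold. The NK cell markers stood at percentile 0.040 and the plasma cell markers at percentile 0.030, the latter with Irf4 3.09-fold and Tnfrsf17 at least 3.83-fold higher in the CD4+ array. Platelet markers had a median of 0.59 over 7 genes (percentile 99.9; 0.34 with normexp and 0.40 with the series values) but a mean of 0.01. The platelet gene Itga2b was at least 2.32-fold higher in the CD8+ array and the integrin gene Itgb3 9.87-fold higher in the CD4+ array. Neutrophil markers had a median of -0.03 over 9 genes (percentile 65.1), positive with normexp, with the series values with median, quantile and loess scaling and with genes of both arrays alone, and stromal and endothelial markers 0.10 over 8 (percentile 89.0). The erythroid list had 4 and the gamma-delta and NKT list 3 members above background, under the minimum of 5. Of these, the hemoglobin gene Hba-a1 differed by -0.30, the scavenger receptor gene Cd163l1 was 4.06-fold higher in the CD8+ array and the interleukin 17 receptor chain gene Il17re at least 5.72-fold higher in the CD4+ array. With normexp the differences of Gpr141b, Wfikkn2, Gulo, Cyp2b9, Cd40lg, Il2, Il21, Il18rap, Ccr4, Itgam, Itga2b, Ncr1, Il17re, Tnfrsf17 and Irf4 lay under 2-fold.

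**Figure D3:**
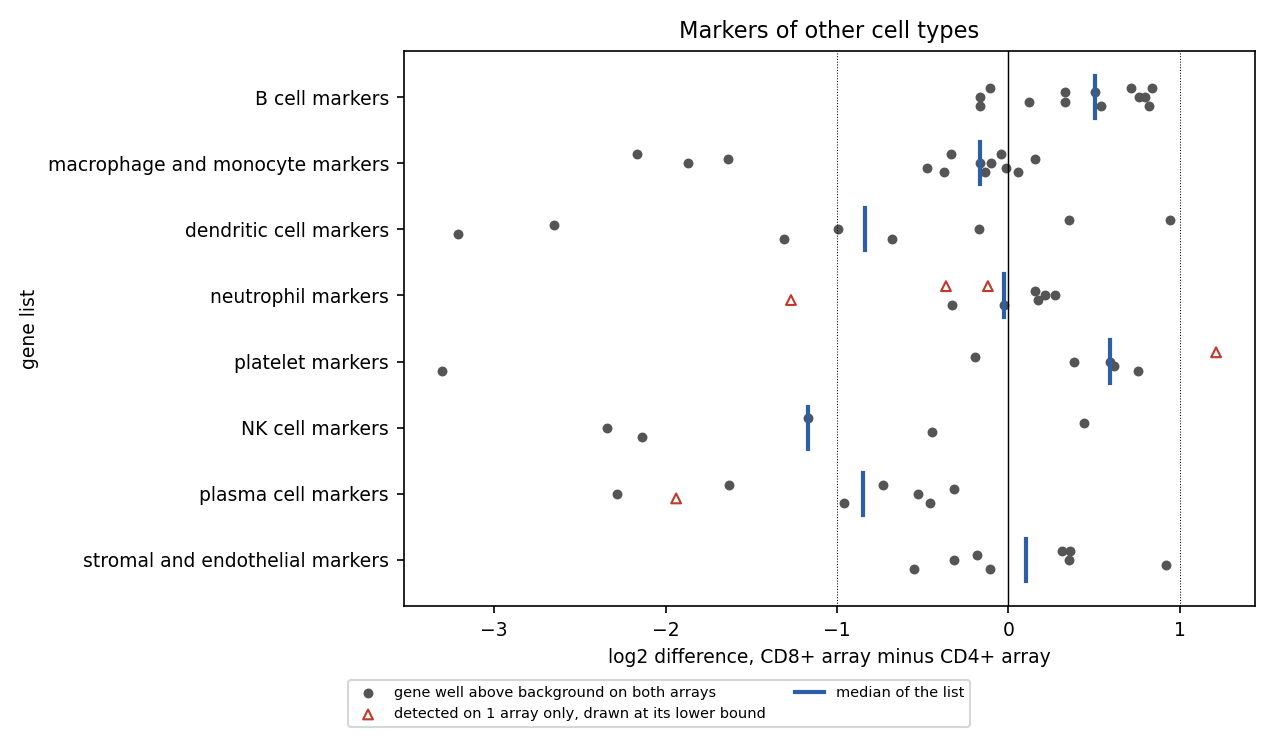
Each row is a list of markers of another cell type and each point a member gene, placed by its log2 difference, CD8+ array minus CD4+ array; open triangles are genes well above background on 1 array alone, drawn at their lower bound, blue bars are medians with those bounds and dotted lines mark 2-fold. B cell and platelet markers have medians of 0.51 and 0.59, and dendritic, plasma and NK cell markers have -0.84, -0.85 and -1.17.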

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

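Probes without a gene symbol fall outside the comparison of named genes, and counting them was not among the choices made before the data were examined. Of 6603 such probes well above background on both arrays, 12 were at least 4-fold higher in the CD8+ array and 30 at least 4-fold higher in the CD4+ array. At 2-fold the counts were 95 and 173. The largest difference in favour of the CD8+ array was 11.2-fold (probe A_52_P505038) and in favour of the CD4+ array 15.3-fold (probe A_51_P118945). No explanation was tested for these probes.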

How the results depend on the processing

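The alternatives were planned, and none was added after the results were seen. No paired analysis was possible because each group held 1 array, and the slide could not be fitted as a block for the same reason. No called value changed sign. With brighter probes alone, the helper cytokine, NK-type receptor, dendritic, NK, plasma and platelet lists kept fewer than 5 genes and gave no value. The 15 lists outside the central range kept their sign in all 189 alternative values, of which 19 differed from the main median by over 1.5 times in size and 3 lay inside that range, 1 of the B cell and 2 of the macrophage list. The 10 lists inside it had 53 of 128 values over 1.5 times apart in size, 5 outside the range, and 13 changes of sign in the chemokine receptor, interferon-stimulated, glycolysis and neutrophil lists. Of 1395 single-gene values 164 moved by more than the SD of 0.23 between probes, 136 of them with normexp or the series values, and those 136 were all smaller in size than the main values; 16 changed sign, all in Klf1, Slc4a1, Alas2, Xist, Ddx3y, Eif2s3y and Kdm5d. Genes at least 2-fold higher in the CD8+ and CD4+ arrays numbered 234 and 458, against 122 and 220 with normexp, 140 and 269 with the series values, 616 and 1277 with no filter on dim probes, 102 and 133 with brighter probes alone and 51 and 111 at 4-fold. Genes of 1 array with a 2-fold bound numbered 54 and 151, against 2 and 18 with normexp, 8 and 25 with the series values and 0 and 0 with brighter probes alone; quantile normalization gave 82 for the CD8+ array, and having no filter leaves no such genes. The regulatory T cell median of -2.07 became -1.25 with normexp, -1.42 with the series values, -2.36 with the mean over probes and -1.54 both with brighter probes and with genes of both arrays alone. The helper cytokine median of -2.14 became -0.93 with normexp, -1.07 with the series values, -1.59 with no filter and -1.5 with genes of both arrays alone. The follicular helper median of -0.79 became -0.53 with normexp, and the cytotoxic median of 0.09 became 0.56 with brighter probes alone. The sort marker Cd4 went from -2.04 to -1.37 with normexp and -1.52 with the series values. The normexp offset of 50 and the background left in the series values lift dim signals by construction, and a stricter filter tests fewer genes; other causes were not tested. Normexp also replaces the processed by the median signal, so its values do not isolate the background correction. Low signal over background limits dim genes.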

Other observations

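The tests in this part on the macrophage and monocyte list, on the NK cell markers as a source in the CD8+ array and on the spread of the cytotoxic list after loess were chosen after the results were seen. The sets of further dendritic cell, NK cell and effector genes were drawn up after the top-ranked genes had been seen and before their own values were. A requirement that such a set's percentile lie outside the central range of the random lists was added after the values were seen, and without it the NK cell set would count in favour of its explanation.

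Genes of different dendritic cell subsets pointed to different arrays. Cd207, 11.96-fold higher in the CD8+ array (7.60-fold with normexp), was joined by Ifi205 (5.34-fold), Rab7b (4.32-fold), the RNA sensor gene Tlr3 (at least 4.19-fold) and Hepacam2 (3.41-fold). All of these are found in the CD8 alpha-bearing conventional dendritic cells of the spleen. Xcr1, a chemokine receptor of the same cells, was 1.28-fold and Cst3 1.92-fold higher in that array. Plasmacytoid dendritic cell genes were higher in the CD4+ array, Siglech by 6.28-fold (3.26-fold with normexp), Cox6a2 by 6.69-fold and Upb1 by 6.52-fold. Cd209a (9.25-fold, or 2.55-fold with normexp) and Clec10a (6.03-fold), lectin genes of other conventional dendritic cells, were higher there too. Cd207, Siglech and Cd209a are named by the rule and Xcr1 and Cst3 belong to the fixed dendritic cell list, and the other genes, like the choice of Xcr1 and Cst3 for mention, came after their values were seen. Of the 8 members of that fixed list above background, only Xcr1 and Cst3 were higher in the CD8+ array. Batf3 and Irf8, also of that list, were not.

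A hypothesis is that RNA of dendritic cells that carry CD8 alpha or CD4 on their surface entered the sorted cells of each array. More macrophages of every kind in the CD4+ array would not raise genes of the CD8 alpha type in the CD8+ array. There 7 of 7 such markers not seen before were higher (median 0.71), which argues against macrophages for those genes. For the genes higher in the CD4+ array, a contribution of macrophages stays undecided. The 13 macrophage and monocyte markers had a median of -0.17 at percentile 0.79, from 0.25 to 7.35 over the alternatives, with Lyz2 at -2.17 and C1qb at 0.15. Markers not seen before went with the hypothesis: 7 genes of the CD8 alpha type had a median of 0.71 (percentile 99.99), 6 of the CD4 type -0.60 (percentile 0.62) and 12 plasmacytoid genes -0.49 (percentile 0.020), and no other list holds any of them. The medians ranged over the alternatives from 0.63 to 0.86, from -0.64 to -0.22 and from -0.54 to -0.35 (brighter probes alone kept fewer than 5 genes of each conventional set), the CD4-type set stood at percentile 3.2 with normexp, and brighter members were not uniform, with Naaa at 1.56 but Cadm1 at 0.01 in the CD8 alpha set, Sirpa at -0.64 in the CD4 set, and Lair1 at -0.88, Pacsin1 at -0.21 and Ugcg at 0.30 among the plasmacytoid genes. Expression of these genes by the T cells themselves stays open, as some, such as Tcf4, Lair1 and Cd24a, are not exclusive to dendritic cells, and the labels name no gate that would remove such cells. Cd24a stood at the median of the CD8 alpha set, and B cell markers were also higher in the CD8+ array, with a median of 0.51. That set was not tested apart from B cell RNA.

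The cytotoxic list was split between the arrays. For RNA of NK cells in the CD8+ array as the source of its higher members, the NK cell markers had a median of -1.17 over 5 genes. It was lower in that array, from -1.22 to -0.69 over the alternatives, at percentiles up to 0.15. That median was the value of the adaptor gene Tyrobp. The NK-type receptors and adaptors, which share genes with this list, had a median of 0.50, with 11 of 14 genes higher in the CD8+ array. They include several near-identical Ly49 genes, so these genes may not be separate measures, and brighter probes alone kept 3 genes. The markers therefore cannot decide whether NK cell RNA contributed there. For an intensity-dependent bias, the median absolute difference of the 18 members was 1.28 before and 1.28 after loess. Loess moved the genes measured on both arrays by a median of -0.04. A spread of that size could therefore hardly fall, and the comparison decided nothing. Gzmm and Fasl, at similar mean levels of -0.60 and -0.53, differed by 3.28 and -3.38. A bias that depends on level alone would move both the same way, so this pair argues against it as the whole cause. The planned test, the list's median after loess (0.026), also decided nothing for a list that goes both ways. For the members higher in the CD4+ array, a larger share of effector and memory T cells may contribute, as 10 genes of such cells had a median of -0.33 (percentile 0.030, -0.38 to -0.19 over the alternatives, at percentiles up to 0.15), with Cd44 at -0.95 and Anxa1 at -0.83 but Ahnak at 0.69 and S100a11 at 0.15, although myeloid cells also express most of them. RNA of NK cells in the CD4+ array cannot be told apart, since 5 further NK cell genes had a median of -0.75 at percentile 2.77, from -0.79 to -0.35 over the alternatives with the same 5 genes, at percentiles from 0.65 to 3.15, and 0.18 with no filter, which adds 4 genes not well above background.

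The regulatory T cell genes in the CD4+ array kept their median after loess, at -2.09 against -2.07. Loess moved the genes measured on both arrays by a median of -0.04, so the trend with level that it removes was too small to give this median. It does not address dim signals. The median was -1.25 with normexp and -1.42 with the series values, and 4 of the 16 genes were well above background on 1 array alone. A difference in cell type, the presence of regulatory T cells among CD4+ cells, stays open as a hypothesis, and with 1 array per group a difference between the mice or preparations is not excluded.

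Sensory receptor genes (olfactory, vomeronasal and taste) made up 23 of the 178 genes detected on the CD8+ array alone (12.9%) and 113 of the 919 on the CD4+ array alone (12.3%). They were 305 of the 11961 genes detected on both (2.55%) and 585 of the 4118 on neither (14.2%).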
